A study of Mus musculus with 20 samples.

How the data were processed

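The material was genomic DNA of B16F10 cells, a mouse melanoma line, carrying a pooled CRISPR knockout library. Per the labels' protocols, 100000000 cells were transduced at a multiplicity of infection of 0.3, selected with 2 µg/ml puromycin for 2 days and treated with interferon-gamma, for 2 days at 10 ng/ml and for a time not given at 0.1 ng/ml. The guide library came as M1 and M2, which hold different guides against the same genes, and each was screened on its own at 10 ng/ml and at 0.1 ng/ml. After treatment, cells were sorted on surface MHC-I and PD-L1 into 4 gates, at 10 ng/ml with 20000000 cells sorted and at 0.1 ng/ml with no number given: high for both proteins (double-high), low for both (double-low), high for MHC-I and low for PD-L1 (MHC-I-only), and low for MHC-I and high for PD-L1 (PD-L1-only). Each of the 20 samples is the PCR-amplified guide pool of 1 population, screen and guide library, and replicate 1 is M1 and replicate 2 is M2.

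The deposited values are counts of sequencing reads per guide, whole numbers not yet normalized, in 4 tables of 92907 guides. MAGeCK is named in the submitters' processing notes, with no version, and so is the genome build mm10. How reads were matched to guides is not given in the sources used here. Every column of counts was assigned to a sample through the population in its own name and the screen and guide library in the name of its table, and 0 columns of counts were left unused.

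Guide names carry the gene and the position of the target site. Gene names were matched to a RefSeq table of the assembly GRCm38.p6, which is the mm10 build. Of the names tested, 17480 equalled a symbol, 889 were found as a synonym and 119 had no match. Of the guides whose gene has a position in that table, 99.1% lay inside the gene, allowing a margin of 50 bp. A month, as a spreadsheet writes it, stood in place of 23 gene names, which were kept as they are and are not named here, and 2 of these, with guides of 2 genes each, were left out. Non-targeting control guides numbered 248 in M1 and 249 in M2, and guides against safe genomic sites 342 and 344. Only 23 guides were shared by name between M1 and M2.

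Most genes had 5 guides per guide library (18396 genes in M1 and 18396 in M2), and 18488 genes with guides in both were tested. The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The planned main test was edgeR's quasi-likelihood F test on guide counts summed per gene and library, two-sided, with TMM factors, a mean summed count of at least 50, the guide library as a block, all 10 libraries of a screen in the fit, and Benjamini-Hochberg adjustment at 0.05. It left 4 residual degrees of freedom, and its common dispersion was 1.974 in the high-dose fit and 0.9767 in the low-dose fit. The difference between doses and the unsorted comparison used all 20 libraries.

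A further test, also fixed beforehand, worked on single guides. The log2 ratio of counts per 1000000 reads (CPM) plus 1 was ranked within each guide library, and the up to 10 ranks of a gene were combined by modified robust rank aggregation with an alpha of 0.25. It was run one-sided in each direction against 10000000 simulated gene sets of the same size with uniform random ranks. The smallest p is therefore 1e-07, and Benjamini-Hochberg adjustment was made within each direction. DESeq2 on the same sums and, chosen after the data were seen, limma on the mean over guides of log2 CPM plus 1 (centred on the median gene, with 1 weight per gate) were further alternatives. The p-values of edgeR, DESeq2 and limma are two-sided.

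Each tool was tested on simulated data drawn from the real guide abundances, with as many sampled genomes per gate as give the observed share of guides without reads (16800 to 11069900 over the sorted libraries) and with 100 genes raised 4-fold and 100 raised 16-fold among 18488 in each gate. All guides of a raised gene were raised by the same factor, and no guide was made inactive or very frequent in single gates. Recovery and error rates in the real screens may therefore be worse than those given here. The edgeR test recovered 0% of the 4-fold and of the 16-fold genes in all 6 simulated comparisons. Rank aggregation recovered the following shares of the genes raised 16-fold against the double-high gate at high dose: 99% in the double-low gate, 93% in the PD-L1-only gate and 98% in the MHC-I-only gate. For genes raised 4-fold the shares were 13%, 5% and 14%. Against the double-low gate at low dose it recovered 98% of the 16-fold genes in the double-high gate, 100% in the MHC-I-only gate and 100% in the PD-L1-only gate, and 26%, 35% and 95% of the 4-fold genes. It called between 2 and 8 unchanged genes higher and 0 lower per simulated comparison. DESeq2 called 243, 3602, 673, 861, 450 and 2 genes lower in these comparisons, where none had been lowered, and 115 and 54 unchanged genes higher in the double-high and MHC-I-only gates at low dose. In the same order limma called 17, 36, 20, 26, 2 and 5 unchanged genes higher and recovered 33%, 26%, 37%, 47%, 52% and 96% of the 4-fold genes and 99% to 100% of the 16-fold ones. For this reason the genes below are those of rank aggregation, with the edgeR, DESeq2 and limma counts beside them.

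From the non-targeting guides, 49 mock genes were made and ranked with the others. None passed in any comparison, and between 1 and 4 had an unadjusted p under 0.05 in the higher direction where 2.45 were to be found by chance. In the lower direction the number ran from 2 to 17, so a lower call in a rarely filled gate is less well calibrated. The mock genes do not test the higher direction for genes of low starting abundance. Of the 1849 genes with the lowest unsorted abundance, 5.5% to 16.2% had an unadjusted p under 0.05 in that direction. This holds for the comparisons of a rarely filled gate with a filled one, where higher calls of such genes are less well calibrated too.

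For a named gene, the text gives the mean over M1 and M2 of the log2 ratio of summed CPM plus 1, with the SD of the 2 values, and CPM values are sums over the gene's guides. The rule for names took the called genes of the edgeR test with the largest change and the same sign in both guide libraries, which gave none, and any member of 21 fixed gene lists. Genes outside the lists were therefore chosen after their values were seen. Pax3, Tyr and Slc45a2 of the melanocyte list were not among the genes tested. Some results of single genes are not reported here.

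Lists were tested with camera on the edgeR counts, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 168 tests, two-sided. An estimated correlation, fry and camera on the limma values were alternatives. Camera on edgeR counts made 14 calls, of which 0 held with an estimated correlation (smallest adjusted p = 0.0968) and 5 held with fry, and on the limma values it made 21 calls, of which 5 held with an estimated correlation and 15 with fry.

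Samples with the same replicate number share a guide library, which is the pairing the labels give. Deviations from the group means correlated between same-numbered samples in all 10 pairs of groups of each screen, from 0.124 to 0.933 at high dose and from 0.206 to 0.945 at low dose, so the guide library was kept as a block. Other alternatives were scaling to the control guides, no count filter, no replicate block, sums without the top guide of each gene, robust empirical Bayes, all 20 libraries in 1 fit, each library left out in turn, a minimum of 50 unsorted reads per guide, a pseudocount of 10, both directions adjusted together, and removal of 15 guides found in opposite gates. These last guides had at least 300 CPM and at least 4-fold more than in unsorted cells in 2 gates that are opposite in both markers, and that rule was set after the data were seen. A range with 1 library or guide library left out joins CPM ratios within 1 guide library and edgeR log2 fold changes without 1 library. In such an edgeR fit 1 group holds a single guide library and is compared through the block, not within a guide library. A range can therefore turn sign where the ratios in M1 and M2 have the same sign.

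The median gene had a log2 CPM ratio between -4.1 and 0.28 in the comparisons of gates, and TMM moved it by -0.57 to 0.4 and control-guide scaling by -0.67 to 0.68. Ratios in the text are on the CPM scale without that shift, except values by a named tool, values without top guides and ranges that include edgeR fits. Ranks were computed on CPM plus 1 and were not repeated with TMM or control-guide scaling. Such scaling can change the ranks of guides with few reads. Total reads per library ran from 2215982 to 65013232, which puts 3 reads at 0.046 to 1.354 CPM, a floor for reads that leaves out how many genomes were sampled.

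Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0) were used.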

Results

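Guides against genes of the mouse genome were counted in B16F10 melanoma cells after sorting on 2 surface proteins that interferon-gamma induces: MHC-I, which presents peptides to T cells, and PD-L1, an inhibitory ligand of T cells. The high-dose screen, at 10 ng/ml interferon-gamma, was meant per the labels to find genes needed for either protein, and the low-dose screen, at 0.1 ng/ml, to find genes that restrain them. Each screen holds 5 populations, an unsorted one and the double-high, PD-L1-only, MHC-I-only and double-low gates, with 2 libraries each, 1 per guide library. The labels name no separate cultures beyond the guide library. The p-values of edgeR, DESeq2 and limma measure the spread between these samples, which may be technical. Those of rank aggregation compare the ranks of a gene's guides with random ranks. They count the guides of both guide libraries as independent and measure no spread between samples. Where n = 2 stands beside them, it counts the guide libraries. Intervals and floors cover counting error only, since reads of PCR products are not independent molecules.

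Depth differed strongly between gates. Unsorted libraries had 28805501 to 58049085 reads and 1% to 3.1% of guides without a read. At high dose the double-high gate had 29294102 and 41335786 reads and 3.1% to 4.1% of guides without one. The other gates of that screen had 2215982 to 12982699 reads, and the share of guides without a read was 81.7% to 85.1% in the PD-L1-only gate, 68.6% to 75.3% in the MHC-I-only gate and 55.6% to 76.4% in the double-low gate. At low dose the double-low gate was the filled one, with 33647996 and 65013232 reads and 1.6% to 3.8% of guides without one. There the PD-L1-only gate lacked 16.1% to 31.7% of guides, the MHC-I-only gate 55.5% to 60.7% and the double-high gate 59.1% to 68.3%. In these rarely filled gates, guides with at least 10 reads had a median of 104 to 343 reads. The share without reads is that of 16800 to 443900 sampled genomes for 92907 guides, by a Poisson model of sampling from the unsorted shares. A guide without reads there may not have been sampled and cannot be called absent.

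**Figure D1:**
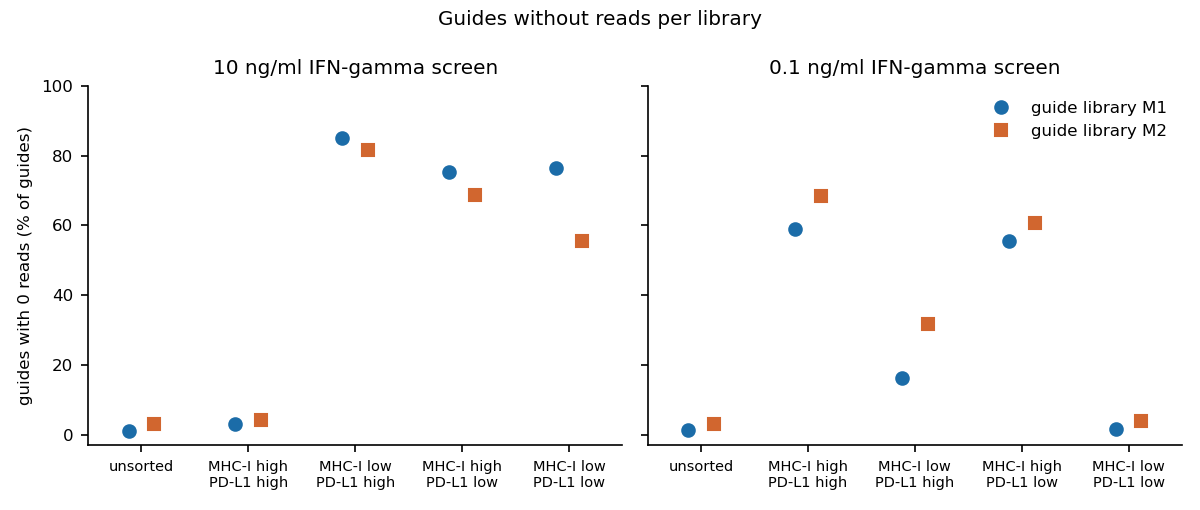
Share of guides without a read (percent, vertical axis) in each population of both screens, with 1 point per guide library. In the PD-L1-only gate at high dose 81.7% to 85.1% of guides had none, against 1% to 3% in unsorted cells of that screen.

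Some guides were frequent in gates that exclude each other. In all, 15 guides, against Ddx41, Eftud2, Ezh2, Jak1, Jak2, Rhbdd1, Srp14, Srsf1 and safe genomic sites, had at least 300 CPM and 4-fold more than in unsorted cells in 2 gates opposite in both markers. A Rosa26 guide took 9.38% of the reads of the PD-L1-only gate at high dose with M2 and 9.47% of the double-high gate at low dose with M2. Ranks were computed with and without these guides, and a call over all genes that rested on them is named as such in the comparison it belongs to. Calls adjusted over a list alone were not repeated without them.

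**Figure D2:**
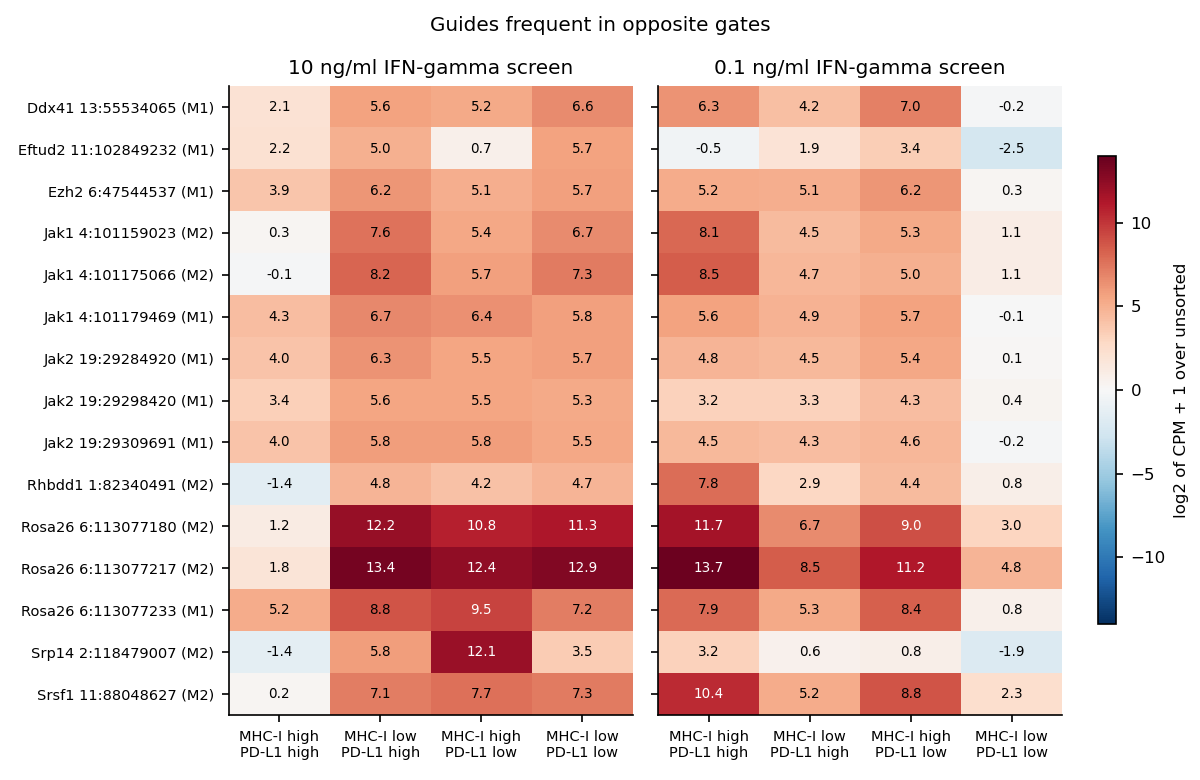
Log2 CPM plus 1 of 15 guides relative to unsorted cells (colour) in the 4 gates of each screen (columns), for the guides found in opposite gates. A guide against the Rosa26 safe site had a log2 value of 8.82 in the PD-L1-only gate and 9.51 in the MHC-I-only gate of the high-dose screen with M1.

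The first high-dose comparison set the double-low gate over the double-high gate and asks which genes both proteins need. Guides against the interferon-gamma receptor and its signalling chain were more frequent in the double-low gate. The receptor chain Ifngr1 had a log2 ratio of 6.37 ± 0.24 (SD, n = 2), with 5776.4 and 2673.1 CPM in the double-low gate against 61.2 and 35.3 in the double-high gate. The other receptor chain, Ifngr2 (6.3 ± 0.67), and the receptor-associated kinases Jak1 (5.74 ± 1.58) and Jak2 (3.76 ± 2.7) were higher too, each with an adjusted p of 0.000205 (n = 2). Of the 6 genes of this list 5 were higher over all genes tested and 6 adjusted over the list alone. Irf1, a transcription factor induced by the pathway, had a log2 ratio of 0.74 ± 1.84, from -0.56 to 2.04 with 1 library or guide library left out. Camera on edgeR counts called the list up (adjusted p = 5.92e-20, and adjusted p = 0.0968 with an estimated correlation).

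Guides against the structural genes of both proteins were also more frequent in that gate. Cd274, which encodes PD-L1 (chromosome 19, 29362107 to 29388095), had a log2 ratio of 5.92 ± 0.18 (SD, n = 2, adjusted p = 0.000205). H2-K1, an MHC-I heavy chain gene, had 4.21 ± 0.83 and the light chain gene B2m (chromosome 2, 122147687 to 122153082) 3.61 ± 0.22, each with an adjusted p of 0.000205. The peptide transporter gene Tap1 (2.21 ± 2.05, adjusted p = 0.00118) and Tapbp, which bridges the transporter and MHC-I (2.58 ± 0.09, adjusted p = 0.017), passed as well. Tap2, the other transporter chain (2.53 ± 0.53), and Nlrc5, the transactivator of MHC-I genes (2.61 ± 0.25), did not pass over all genes, with adjusted p of 0.329 and 0.152. The list of MHC-I assembly and peptide loading thus had 4 of 11 members higher and 6 adjusted over the list alone. H2-D1, another heavy chain gene of the list, passed in neither way. Camera called the list up (adjusted p = 4.03e-09, and adjusted p = 0.107 with an estimated correlation). For MHC-I transcription the numbers were 0 of 8 and 1 adjusted over the list alone, with 0 by edgeR and 1 by limma (camera adjusted p = 0.00355, and adjusted p = 0.587 with an estimated correlation). For PD-L1 and its turnover they were 1 of 9 and 2 adjusted over the list alone, the added gene being Cul3, a ubiquitin ligase scaffold.

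Rank aggregation called 19 genes higher and 1 lower of 18488. Of those outside the lists, chosen after their values were seen, Wdr1, which takes part in actin filament disassembly, had a log2 ratio of 3.67 ± 0.08 (SD, n = 2, adjusted p = 0.000205), and the mitotic kinase genes Aurkb (4.37 ± 0.22, adjusted p = 0.00262) and Mastl (3.9 ± 2.09, adjusted p = 0.0107) rested on 4 and 3 guides with at least 10 reads, Mastl with -2.95 by edgeR without its top guides. Dbr1, which debranches intron lariats, had 2.7 ± 0.02 (adjusted p = 0.0435) and Neurod1, a neuronal transcription factor, 1.67 ± 0.75 (adjusted p = 0.0331). The 1 lower gene, Marcks, a substrate of protein kinase C, had -1.07 ± 0.29 (adjusted p = 0.0481), in a direction in which 12 of 49 mock genes had an unadjusted p under 0.05 where 2.45 were to be found by chance. Dbr1 and Marcks no longer passed with guides of 50 or more unsorted reads, nor did they or Mastl with a pseudocount of 10, and Alg2, Dbr1 and Neurod1 did not with both directions adjusted together. The edgeR test called 0 genes, with 474 at an unadjusted p under 0.05, DESeq2 called 8 higher and 265 lower, and limma 25 higher, 17 of them also called by rank aggregation. With M1 alone 6 genes passed rank aggregation and with M2 alone 11.

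**Figure D3:**
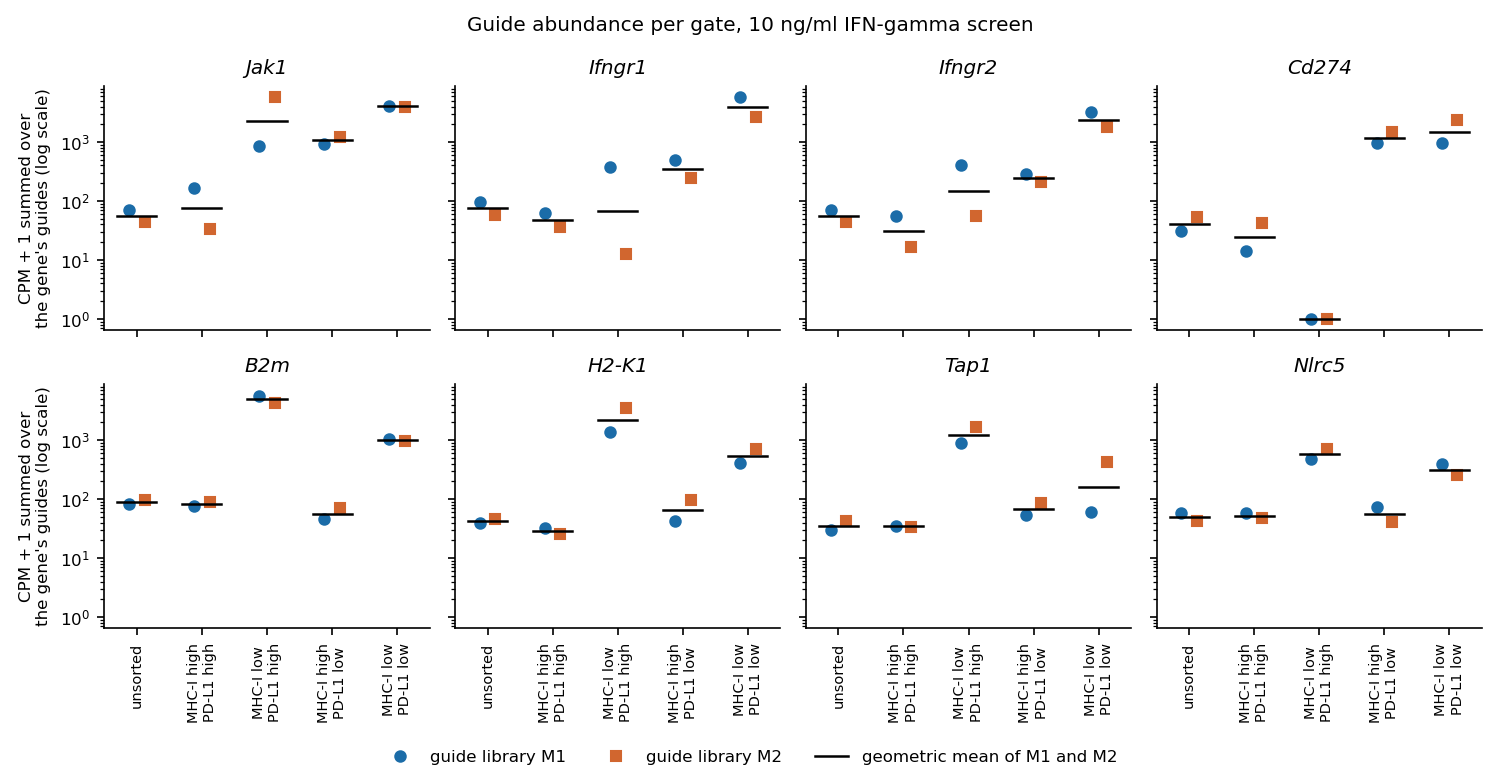
CPM plus 1 (log axis) of 8 genes in the 5 populations of the high-dose screen, with 1 point per guide library and a line at the geometric mean. Ifngr1 had 5776.4 and 2673.1 CPM in the double-low gate against 61.2 and 35.3 in the double-high gate, and Cd274 had no read in the PD-L1-only gate.

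Genes needed for MHC-I rather than PD-L1 were asked for by setting the PD-L1-only gate over the double-high gate. MHC-I genes led this comparison: H2-K1 had a log2 ratio of 6.27 ± 1.21 (SD, n = 2), B2m 5.89 ± 0.44, Tap1 5.13 ± 0.71 and Tapbp 4.02 ± 0.66, each with an adjusted p of 0.000308, and Tap2 had 4.3 ± 1.14 (adjusted p = 0.0429). B2m guides made up 5731 and 4254 CPM in the PD-L1-only gate against 76.9 and 87.7 in the double-high gate. Of the 11 genes of MHC-I assembly 5 were higher over all genes and 5 adjusted over the list alone (camera on edgeR counts, adjusted p = 1.99e-09, and adjusted p = 0.107 with an estimated correlation). The heavy chain gene H2-D1 passed in neither way.

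The regulators of MHC-I transcription were the other group. Nlrc5 (3.48 ± 0.59, SD, n = 2, adjusted p = 0.0379) and Rfxap, a subunit of the RFX complex that binds MHC promoters (2.89 ± 0.73, adjusted p = 0.00185), were higher, while the further RFX subunits Rfx5 and Rfxank, with 3.27 ± 0.48 (-0.75 by edgeR without its top guides) and 2.34 ± 0.35, did not pass over all genes. Nlrc5 and Tap2 no longer passed with guides of 50 or more unsorted reads (adjusted p = 0.0561 and 0.0538) or with both directions adjusted together, and Rfxap passed under both. In all, 2 of 8 members passed, and 6 adjusted over the list alone (camera adjusted p = 4.51e-06, and adjusted p = 0.431 with an estimated correlation). In the interferon-gamma list Jak1 alone passed (4.89 ± 3.56, adjusted p = 0.00159), and it no longer did when guides found in opposite gates were left out (adjusted p = 0.737). Ifngr1 had 0.52 ± 2.91 (-1.74 to 2.58 with 1 library or guide library left out), and 5 of 6 passed adjusted over the list alone (camera adjusted p = 5.24e-07, and adjusted p = 0.148 with an estimated correlation).

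Rank aggregation called 13 genes higher and 0 lower in this comparison, with 1149 at an unadjusted p under 0.05 in the lower direction. Outside the lists and chosen after their values were seen, Dhps, the first enzyme of hypusine formation on eIF5A, had a log2 ratio of 4.42 ± 0.22 (SD, n = 2) and Dbr1 4.48 ± 0.79, both with an adjusted p of 0.000308, and Sfr1, which acts in recombination repair, 3.68 ± 1.58 (adjusted p = 0.0345). The kinesin gene Kif18a (1.52 ± 0.24) and Anapc2 of the anaphase-promoting complex (3.78 ± 0.87) had adjusted p of 0.0478 and 0.0479, and 0.0518 each without the guides found in opposite gates, and Kif18a had -8.81 by edgeR without its top guides. Both were also lost with guides of 50 or more unsorted reads and, like Sfr1, with both directions adjusted together. By edgeR 0 genes passed, with 3433 at an unadjusted p under 0.05, by DESeq2 12 were higher and 4356 lower, and by limma 24 were higher, 12 of them shared with rank aggregation. With M1 alone 3 genes passed rank aggregation and with M2 alone 8.

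The converse comparison, the MHC-I-only gate over the double-high gate, asks for genes that PD-L1 needs and MHC-I does not. Cd274 was higher, with a log2 ratio of 5.58 ± 0.66 (SD, n = 2, adjusted p = 0.000924) and 947 and 1470 CPM against 13.3 and 41.3. In the interferon-gamma list Jak1 (3.84 ± 1.9, adjusted p = 0.000924), Ifngr2 (3.02 ± 0.91, adjusted p = 0.0151) and Ifngr1 (2.88 ± 0.15, adjusted p = 0.00878) were higher. That is 3 of 6 members over all genes and 5 adjusted over the list alone (camera adjusted p = 1.48e-09, and adjusted p = 0.107 with an estimated correlation). The list of PD-L1 and its turnover had 1 of 9 members higher and 1 adjusted over the list alone. MHC-I assembly had 0 of 11 members higher and 0 adjusted over the list alone, with 0 by edgeR and 0 by limma, and camera called it up all the same (adjusted p = 0.0114, and adjusted p = 0.463 with an estimated correlation).

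Rank aggregation called 6 genes higher and 0 lower in the MHC-I-only gate, with 1117 at an unadjusted p under 0.05 in the lower direction. The 2 called genes outside the lists, chosen after their values were seen, were Srp19 (log2 ratio 3.32 ± 1.53, SD, n = 2, adjusted p = 0.00878) and Srp14 (7.01 ± 6.53, adjusted p = 0.00961), subunits of the signal recognition particle that directs nascent proteins to the endoplasmic reticulum. Srp14 no longer passed without the guides found in opposite gates (adjusted p = 0.277), Srp19 with guides of 50 or more unsorted reads (adjusted p = 0.28) or a pseudocount of 10 (adjusted p = 0.167), and Ifngr1 with that pseudocount (adjusted p = 0.0525). The edgeR test called 0 genes with 907 at an unadjusted p under 0.05, DESeq2 4 higher and 665 lower, and limma 10 higher, 6 of them shared with rank aggregation. With M1 alone 1 gene passed rank aggregation and with M2 alone 3.

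Set directly against each other, the MHC-I-only and PD-L1-only gates separate genes by which of the proteins they act on. Cd274 was higher in the MHC-I-only gate (adjusted p = 0.00185, n = 2), with 947 and 1470 CPM against 0 reads in both libraries of the PD-L1-only gate. No fold is given, since that gate held only 16800 and 20900 sampled genomes by the same Poisson model. Lower in the MHC-I-only gate were B2m, with a log2 ratio of -6.45 ± 0.75 (SD, n = 2), H2-K1 (-5.1 ± 0.12), Tap1 (-4.16 ± 0.16), Tapbp (-3.13 ± 0.5) and, outside the lists and chosen after its values were seen, Dhps (-6.68 ± 3.24), each with an adjusted p of 0.00037. MHC-I assembly had 4 of 11 members lower and 6 adjusted over the list alone (camera adjusted p = 0.00994, and adjusted p = 0.466 with an estimated correlation). H2-D1 was lower only adjusted over the list alone. MHC-I transcription had 0 of 8 lower and 6 adjusted over the list alone, with 0 by edgeR and 0 by limma (camera adjusted p = 0.0031, and adjusted p = 0.587 with an estimated correlation). These 6 genes were all of the rank aggregation calls and limma called the same 1 higher and 5 lower. By edgeR 0 passed, with 2652 at an unadjusted p under 0.05, and by DESeq2 3224 were higher and 660 lower. With M1 alone 1 gene passed rank aggregation and with M2 alone 3.

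The low-dose screen turned the direction around, and its first comparison, the double-high gate over the double-low gate, asks which genes restrain both proteins. Stub1 (chromosome 17, 25830634 to 25832919), a ubiquitin ligase that works with heat shock proteins, was higher, with a log2 ratio of 6.47 ± 1.78 (SD, n = 2, adjusted p = 0.000924). Its guides made up 2045 and 769 CPM in the double-high gate against 8.68 and 19.8 in the double-low gate, and 10 of 10 had at least 10 reads. It was the 1 of 12 negative regulators of interferon signalling that passed, over all genes and adjusted over the list alone. The inhibitors of JAK kinases and the phosphatases on that list did not pass.

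Outside the lists, and chosen after their values were seen, Ube2n, the conjugating enzyme for lysine-63 ubiquitin chains, had a log2 ratio of 3.3 ± 0.5 (SD, n = 2, adjusted p = 0.00431), Triap1, a mitochondrial lipid transfer chaperone gene, 2.45 ± 0.82 (adjusted p = 0.0139), Cltc, the clathrin heavy chain gene, 3.02 ± 1.66 (adjusted p = 0.0275), Smg1, a kinase of nonsense-mediated RNA decay, 2.53 ± 1.44 (adjusted p = 0.029) and the histone gene H2ac23 2.26 ± 1.15 (adjusted p = 0.0126). Gins4 of the replicative helicase passed at 0.8 ± 2.95 (adjusted p = 0.028), with -1.29 in M1 alone. Of these Cltc, Triap1 and H2ac23 no longer passed with guides of 50 or more unsorted reads, all but Ube2n were lost with a pseudocount of 10, and Cltc, Smg1 and Gins4 with both directions adjusted together. Jak1 (4.36 ± 3.58, adjusted p = 0.000924) and the helicase gene Ddx41 (3.03 ± 4.2, adjusted p = 0.00786) passed only with guides found in opposite gates. Without them they had adjusted p of 0.994 and 0.694, and the ratio of Jak1 turned negative. Jak1 was the 1 of 6 members of the interferon-gamma list to pass, with 2 adjusted over the list alone. Core essential genes had 0 of 20 members higher and 4 adjusted over the list alone, with 0 by edgeR and 0 by limma, and B2m, with -4.45 ± 2.96, was lower adjusted over the list alone.

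These were the 9 genes called higher, with 0 lower and 1157 at an unadjusted p under 0.05 in that direction. The edgeR test called 0 with 949 at an unadjusted p under 0.05, DESeq2 24 higher and 759 lower, and limma 17 higher, 5 of them shared with rank aggregation. With M1 alone 2 genes passed rank aggregation and with M2 alone 4, and without replicate 1 of the double-high gate edgeR called 1537.

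**Figure D4:**
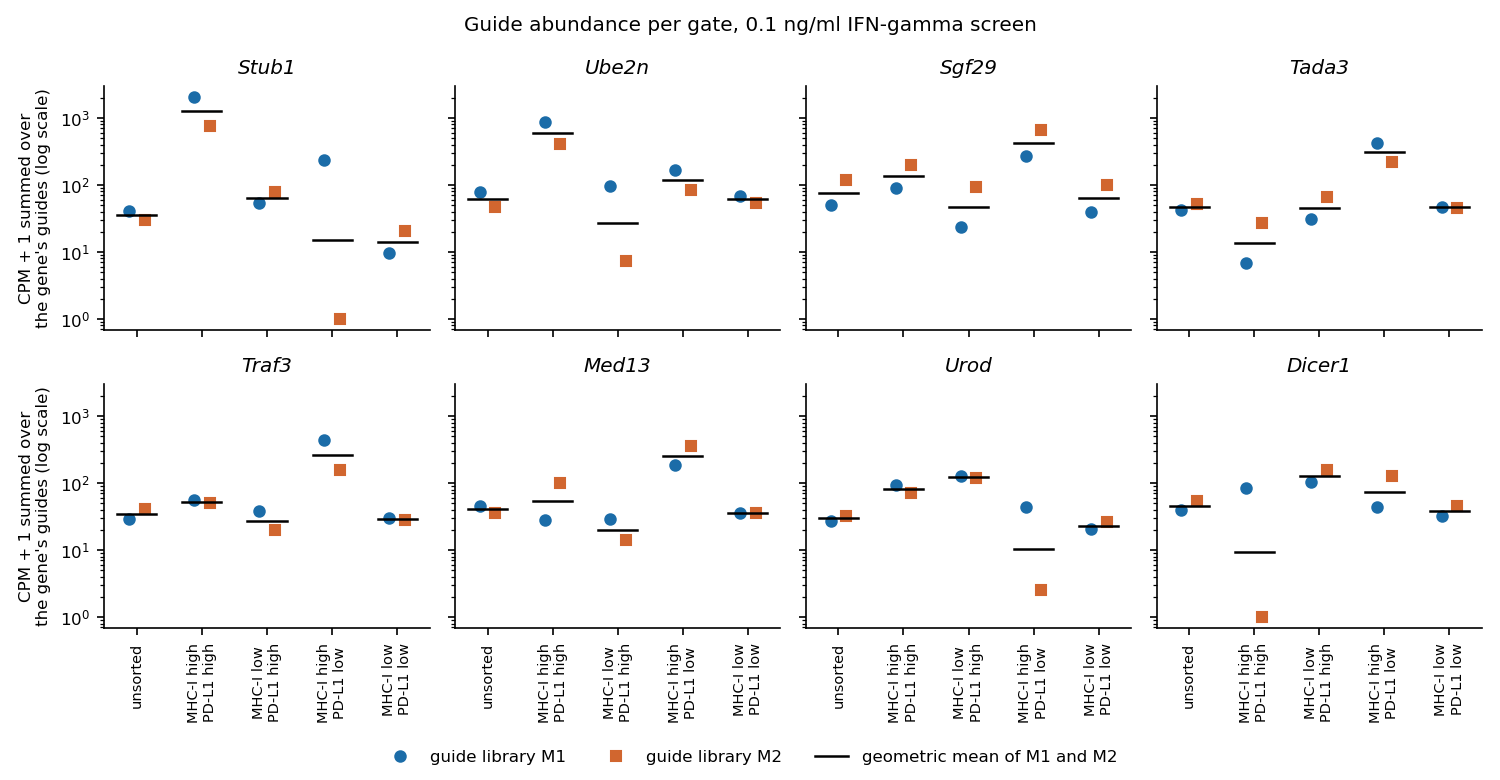
CPM plus 1 (log axis) of 8 genes in the 5 populations of the low-dose screen, with 1 point per guide library and a line at the geometric mean. Stub1 had 2045 and 769 CPM in the double-high gate against 8.68 and 19.8 in the double-low gate.

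Genes that restrain MHC-I but not PD-L1 were sought in the MHC-I-only gate over the double-low gate at low dose. The called gene was Sgf29 (chromosome 7, 126648386 to 126672779), which encodes the histone-reading subunit of the SAGA coactivator complex and was chosen after its values were seen. It had a log2 ratio of 2.75 ± 0.04 (SD, n = 2, adjusted p = 0.0481), with 272 and 665 CPM against 38.6 and 99.9. Tada3, another SAGA subunit gene, had 2.74 ± 0.62, Traf3, an adaptor that holds back non-canonical NF-kB signalling, 3.18 ± 1.01, and Med13 of the Mediator kinase module 2.83 ± 0.66, each with an adjusted p of 0.0666. By limma these 3 passed, with adjusted p of 0.00133, 0.00155 and 0.000239, but without the replicate block limma called 0 genes here.

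Mediator and BET had 0 of 12 members higher over all genes and 4 adjusted over the list alone, Med12, Med13, Med15 and Med19, with log2 ratios from 1.43 to 2.83. By edgeR 0 of them passed and by limma 1 (camera adjusted p = 0.0251, and adjusted p = 0.541 with an estimated correlation, with a list median of -0.23, opposite in sign). NF-kB restraint had 0 of 9 higher and 2 adjusted over the list alone, Traf3 and Traf2 (1 ± 0.29), with 0 by edgeR and 1 by limma. PRC2, which methylates lysine 27 of histone H3, had 0 of 7 higher and 3 adjusted over the list alone, among them Eed (2.31 ± 0.04), with 0 by edgeR and 0 by limma. Rank aggregation called 1 gene higher and 0 lower, with 996 higher and 1146 lower at an unadjusted p under 0.05, edgeR 0 with 1339 in either direction, DESeq2 53 higher and 1122 lower, and limma 7 higher. Sgf29 passed with neither guide library alone and not when both directions were adjusted together, while 3207 genes passed edgeR without replicate 1 of the MHC-I-only gate and 723 without replicate 2.

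For PD-L1 the same question was put to the PD-L1-only gate over the double-low gate at low dose, the best filled of the sorted comparisons. Urod (chromosome 4, 116989965 to 116994436), the uroporphyrinogen decarboxylase of heme synthesis, had a log2 ratio of 2.43 ± 0.34 (SD, n = 2), Stub1 2.17 ± 0.4, Dicer1, which makes microRNAs, 1.77 ± 0.08 and Eftud2, a spliceosomal GTPase gene, 3.38 ± 0.18, each with an adjusted p of 0.000462. Urod guides made up 129 and 117 CPM against 19.5 and 24.9. All but Stub1 lie outside the lists and were chosen after their values were seen, as were the arginine methyltransferase genes Prmt1 (1.43 ± 1.08, adjusted p = 0.00074) and Prmt5 (2.3 ± 0.16, adjusted p = 0.0441).

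The other called genes outside the lists were chosen in the same way. Pabpc1, the poly(A)-binding protein gene, had a log2 ratio of 2.02 ± 1.33 (SD, n = 2, adjusted p = 0.00216), the initiation factor genes Eif3d and Eif6 1.78 ± 1.26 (adjusted p = 0.015) and 1.45 ± 0.79 (adjusted p = 0.0438), the splicing factor gene Prpf18 1.67 ± 1.28 (adjusted p = 0.028) and Gtf2h3 of the transcription factor TFIIH 2.11 ± 0.07 (adjusted p = 0.015). Plekhm2, which links lysosomes to kinesin, and Brat1 had 1.49 ± 0.12 and 1.77 ± 0.58. With guides of 50 or more unsorted reads Pabpc1, Eif3d, Eif6, Prpf18 and Plekhm2 no longer passed, and with both directions adjusted together Eif6, Prpf18, Plekhm2, Brat1 and Prmt5 did not. A pseudocount of 10 ended the calls of Stub1, Eftud2, Prmt1, Prmt5, Pabpc1, Eif3d, Eif6 and Prpf18. Urod, Dicer1 and Gtf2h3 passed under all of these changes, which do not include 1 guide library alone. Jak1 and Jak2 passed with 2.33 ± 1.16 and 0.29 ± 4.37 (Jak2 -3.68 to 3.92 with 1 library or guide library left out), which makes 2 of 6 members of the interferon-gamma list and 2 adjusted over the list alone. Without the guides found in opposite gates both had a negative ratio and an adjusted p of 1, and Prmt5 and Eif6 had an adjusted p of 0.0505. Stub1 was the 1 of 12 negative regulators to pass, and 1 adjusted over the list alone. SWI/SNF, a chromatin remodelling complex, had 0 of 9 members higher and 3 adjusted over the list alone, Arid1a, Arid2 and Smarcb1 (the last from -1.47 to 4.4 with 1 library or guide library left out), with 0 by edgeR and 0 by limma (camera adjusted p = 0.00023, and adjusted p = 0.431 with an estimated correlation). PD-L1 and its turnover had 0 of 9 lower and 2 adjusted over the list alone, Cd274 (-3.68 ± 3.1) and Cul3, with 0 by edgeR and 0 by limma (camera down, adjusted p = 0.0446, and adjusted p = 0.551 with an estimated correlation).

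In this comparison rank aggregation called 15 genes higher and 0 lower, with 1007 at an unadjusted p under 0.05 in the lower direction. By edgeR 0 passed with 4 at an unadjusted p under 0.05, by DESeq2 1 was lower, and by limma 4 were higher, all shared with rank aggregation. With M1 alone 13 genes passed rank aggregation, 7 of them among the 15, and with M2 alone 2.

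Between the MHC-I-only and the PD-L1-only gate at low dose, 0 genes passed rank aggregation, with 1926 at an unadjusted p under 0.05, and 0 passed edgeR, with 1445, while DESeq2 called 111 higher and 1133 lower and limma 6 higher. Of the Mediator list, Med12 had a log2 ratio of 4.99 ± 1.11 (SD, n = 2), Med13 3.65 ± 1.39 and Med19 2.19 ± 0.92, and 0 of 12 members passed over all genes and 6 adjusted over the list alone, with 2 by limma (camera on edgeR counts, adjusted p = 0.00521, and adjusted p = 0.431 with an estimated correlation). By limma, Sgf29 (3.17 ± 0.5, adjusted p = 0.00482) and Tada3 (2.76 ± 1.44, adjusted p = 0.0189) passed as well, and 0 genes did without the replicate block. NF-kB restraint had 0 of 9 members higher and 1 adjusted over the list alone, Traf3 (3.26 ± 0.39), with 0 by edgeR and 0 by limma. Without replicate 1 of the MHC-I-only gate edgeR called 3268 genes and without replicate 2 it called 798.

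The unsorted populations were compared to ask whether guides differed between doses before sorting. Rank aggregation called 9 genes higher at 10 ng/ml and 0 lower, with 967 at an unadjusted p under 0.05 in the lower direction. Nus1 had a log2 ratio of 2.22 ± 0.3 (SD, n = 2) and Prpf38b 3.89 ± 5.92, both with an adjusted p of 0.000924, and Dhdds 1.54 ± 1.88 (adjusted p = 0.00693). Among their guides 1 against Nus1 and 1 against Dhdds, both in M1, and 2 against Prpf38b in M2 took 0.37% to 2.74% of the reads of an unsorted library at high dose. In every sorted gate of that screen these guides were far rarer. The Nus1 guide had 25383.3 CPM unsorted against at most 191.8 in a gate, and the Dhdds guide 3687.8 against 155.2. Those of Prpf38b had 27403.2 and 6804.1 against 486.5 and 596.5. At low dose the Nus1 guide took 0.63% of the unsorted M1 reads. Calls that rest on these guides may not show the cells before sorting, and the cause was not tested. With 1 library or guide library left out Nus1 ran from -4.01 to 8.59, Prpf38b from -0.3 to 8.08, Dhdds from -1.74 to 4.66 and Jak2 from -1.85 to 3.5. These ranges include edgeR fits in which 1 population holds a single guide library. Jak2, the 1 of 6 members of the interferon-gamma list to pass, had 0.76 ± 0.05 (adjusted p = 0.0468), with 3 adjusted over the list alone, and like Eftud2 (2.51 ± 1.24, adjusted p = 0.00493) it did not pass without the guides found in opposite gates. By edgeR without its top guides Eftud2 turned negative. The remaining genes were Cltc, Hspe1, Igbp1 and Nae1, with log2 ratios from 0.51 to 0.69, and all but Jak2 were chosen after their values were seen. Nus1 and Nae1 no longer passed with guides of 50 or more unsorted reads, Cltc, Dhdds, Hspe1, Igbp1 and Nae1 with a pseudocount of 10, and Hspe1, Igbp1, Jak2 and Nae1 with both directions adjusted together. By edgeR 0 passed, with 1 at an unadjusted p under 0.05, by DESeq2 0 and by limma 6, and with M1 alone 0 genes passed rank aggregation and with M2 alone 1. Dose cannot be told apart from screen here.

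In the last comparison, too, dose cannot be told apart from screen. The rarely filled gate of the pair was the double-low one at high dose and the double-high one at low dose. An upward shift of guides with low starting abundance in a rarely filled gate can therefore add up over the 2 screens. That comparison tested whether the ratio of the double-low to the double-high gate differed between doses. It was higher at 10 ng/ml for 5 of 6 genes of the interferon-gamma list, over all genes and adjusted over the list alone, with differences of log2 ratios of 10.1 ± 5.16 (SD, n = 2) for Jak1 (5.01 without the guides found in opposite gates, adjusted p = 0.000308) and 6.11 ± 0.24 for Ifngr1. Cd274 differed by 5.72 ± 0.06 and Stub1, enriched in the double-high gate at low dose, by 3.98 ± 2.05 (-6.97 to 7.7 with 1 library or guide library left out), each of these with an adjusted p of 0.000231. Negative regulators had 1 of 12 members higher and 1 adjusted over the list alone, PD-L1 and its turnover 1 of 9 and 1, and MHC-I assembly 0 of 11 and 2 adjusted over the list alone, with 0 by edgeR and 2 by limma. Rank aggregation called 15 genes higher and 0 lower, with 1072 at an unadjusted p under 0.05 in the lower direction, edgeR 0 with 1041, DESeq2 7 higher and 790 lower, and limma 28 higher and 1 lower. Without the guides found in opposite gates 12 genes passed rank aggregation, with M1 alone 10 and with M2 alone 3.

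Lists not described so far had 0 members past rank aggregation over all genes and 0 past edgeR in the 8 comparisons of gates. Adjusted over the list alone, type I interferon had Stat2 lower and glycosphingolipid synthesis B4galt5 lower in the MHC-I-only gate at high dose, and autophagy had Atg12 and growth suppressors Trp53 higher in the PD-L1-only gate at high dose. At low dose and adjusted over the list alone, Ezh2 and Rbbp4 of PRC2, Birc3, Uhrf1 and Ugcg were higher and Degs1 and Krt5 lower in the PD-L1-only gate over the double-low gate. In the MHC-I-only gate over that gate Sox10 of the melanocyte list, Nfyb, Jak1, Jak2 and Stub1 were higher and Amh lower, and Atg9a was lower in the double-high gate. Without the guides found in opposite gates Jak1 and Jak2 had adjusted p over all genes of 0.977 and 0.989 in that MHC-I-only gate, and Ezh2 0.979 there and 0.942 in the PD-L1-only gate. Between the MHC-I-only and PD-L1-only gates, adjusted over the list alone, Degs1 and Cdkn2c were lower at high dose, and at low dose Spred1 and Trim28 were higher and Smarcb1, Atg9a, Kdm1a and Amh lower. Krt5 and Amh belong to the list of genes of non-melanocyte lineages, not expected to act in this cell line. Adjustment over the list alone thus also called such genes. Immunoproteasome (5 genes), NF-kB activation (12) and MTOR and TSC (13) had 0 members adjusted over the list alone in these comparisons. By limma, 0 of the genes named here passed in the comparison given.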

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

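Of the tests given here, the constancy of ratios between guides and their recurrence at low dose were chosen after the result was seen, as was the rule that found those guides.

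The ratio of the double-low to the double-high gate differed between 10 and 0.1 ng/ml interferon-gamma for 15 genes, by rank aggregation of the difference itself. Dose cannot be told apart from screen here. The rarely filled gate was the double-low one at 10 ng/ml and the double-high one at 0.1 ng/ml, so effects of low starting abundance can add up. Differences of log2 ratios for genes of the fixed lists included 10.1 for Jak1, 6.11 for Ifngr1, 3.56 for Ifngr2, 3.44 for Jak2, 5.72 for Cd274 and 3.98 for Stub1, each with an adjusted p of 0.000231. Outside the lists they were 5.39 for Ddx41 (adjusted p = 0.000231), 3.62 for Ube2n (adjusted p = 0.00924), 4.62 for Mybl2 and 5.21 for Dhdds (adjusted p = 0.0108 each), 3.84 for H2ac23 (adjusted p = 0.0219), and 0.79 for Rpl9, 10.01 for Srsf1 and 4.14 for Srp14 (adjusted p = 0.0439 each). Some of these turned sign with 1 library or guide library left out, with -5.81 to 5.74 for Ifngr2, -7.1 to 6.68 for Jak2, -6.97 to 7.7 for Stub1 and -7.36 to 2.14 for Rpl9. These ranges include edgeR fits in which 1 gate holds a single guide library. By edgeR without top guides Rpl9 had -6.44 and Srsf1 -2.23. Without the guides found in opposite gates the difference was 5.01 for Jak1 (adjusted p = 0.000308), while Ddx41 (5.23), Srp14 (0.32) and Srsf1 (1.89) no longer passed. H2ac23, Rpl9 and Srp14 were lost with guides of 50 or more unsorted reads and with a pseudocount of 10, and Rpl9, Srp14 and Srsf1 with both directions adjusted together.

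Guides against safe genomic sites, which target no gene product and entered no comparison, took 0.536% to 0.567% of the reads of unsorted cells and at least 4-fold more than in unsorted cells in 7 of 16 sorted libraries. In the other 9 it was 0.562% to 1.49%. At high dose their share was 3.351% (M1) and 12.645% (M2) in the PD-L1-only gate, 5.325% (M1) and 6.048% (M2) in the MHC-I-only gate and 8.655% (M2) in the double-low gate. At low dose it was 12.141% (M2) in the double-high gate and 2.545% (M2) in the MHC-I-only gate.

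Much of this share came from single guides, and 15 guides (8 in M1 and 7 in M2), against safe sites and 8 genes including Jak1, Jak2, Ezh2 and Srp14, were far more frequent in gates opposite in both markers than in unsorted cells. A strong effect of the knockout itself in both gates is argued against, since by rank aggregation of their other guides 0 of the 8 genes were called in both opposite gates over unsorted cells. A weaker effect stays open. In the simulation against the double-high gate at high dose, 93% and 98% of 16-fold genes but 5% and 14% of 4-fold genes were recovered in the PD-L1-only and MHC-I-only gates. In each screen 1 gate of the double-high and double-low pair is also filled much like unsorted cells. The other guides were called at high dose in single gates, those of Jak1 in the double-low (adjusted p = 0.000231) and MHC-I-only gates (adjusted p = 0.0425) and those of Jak2 in the double-low gate (adjusted p = 0.000231). Separate outgrowth of single clones in each gate is argued against too, since of 9 guides that met the rule at high dose alone 7 were at least 4-fold over unsorted cells in all 3 rarely filled gates at low dose, against 0.018% of 152695 other guides. Material of a few constructs shared by the sorted libraries may account for the guides, and it was taken to keep the ratio of any 2 of them nearly constant over the 4 gates. The median SD of that log2 ratio over 98 pairs was 1.2, and 36 pairs lay under 1. A value under 1 had been set for shared material and 2 or more against it. The 4 gates include the filled one, where sorted cells may outweigh shared material. A varying ratio would therefore not exclude it, and shared material stays open. Random pairs of guides had a median of 0.87, which leaves the test little power. No biological explanation beyond the knockout and the outgrowth of clones was tested.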

How the results depend on the processing

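The alternatives by limma, the changes to rank aggregation as fixed beforehand (the minimum of unsorted reads, the other pseudocount, both directions together and 1 guide library alone) and the removal of guides found in opposite gates were chosen after the data were seen. In the order double-low, PD-L1-only and MHC-I-only over double-high and MHC-I-only over PD-L1-only at high dose, then double-high, MHC-I-only and PD-L1-only over double-low and MHC-I-only over PD-L1-only at low dose, then unsorted and the difference between doses, the planned edgeR test called 0 genes throughout, with 474, 3433, 907, 2652, 949, 1339, 4, 1445, 1 and 1041 at an unadjusted p under 0.05. In that order DESeq2 called 273, 4368, 669, 3884, 783, 1175, 1, 1244, 0 and 797, rank aggregation 20, 13, 6, 6, 9, 1, 15, 0, 9 and 15, and limma 25, 24, 10, 6, 17, 7, 4, 6, 6 and 29. With all 20 libraries in the fit edgeR called 447 in the PD-L1-only gate at high dose and 473 against the MHC-I-only gate, where it called 1 without top guides, 1 with robust estimation and 2 without the guides found in opposite gates. Control-guide scaling and no count filter left it at 0 in all 10 comparisons. Leaving out 1 library gave 0 to 1537, 0 to 3207 and 0 to 3268 genes in the low-dose comparisons of the double-high and of the MHC-I-only gate over the double-low gate and of the MHC-I-only over the PD-L1-only gate, and 0 in the others. The cause was not tested for any of these, except that the simulated data show that edgeR recovers none and that DESeq2 calls unchanged genes lower.

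Without the replicate block, edgeR called 0 genes in all 10 comparisons and limma 6, 5, 1, 1 and 2 in the 4 high-dose comparisons and the difference between doses, and 0 in the others. The block changed no other call by edgeR.

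Rank aggregation of the MHC-I-only over the double-low gate at low dose called 3 genes with guides of 50 or more unsorted reads, 8 with a pseudocount of 10 and 0 with both directions adjusted together. With a pseudocount of 10 it called 9 in the PD-L1-only gate over the double-low gate, 1 in the MHC-I-only over the PD-L1-only gate and 4 in unsorted cells, where both directions together gave 5. With 1 guide library alone it called, in the order above, 6 to 11, 3 to 8, 1 to 3, 1 to 3, 2 to 4, 1 to 2, 2 to 13, 0 to 2, 0 to 1 and 3 to 10, from fewer guides per gene. Over the alternatives of rank aggregation 37 gene counts stayed within 1.5 times its own and 23 did not, 8 of these with M1 alone and 8 with M2 alone. Counts by edgeR that stay at 0 tell nothing of stability, as it recovers none. Over all alternatives 598 list results stayed on their side of the threshold, while 41 passed and 33 no longer did. Of the results for named genes, 920 kept their call, 36 passed newly, 1434 no longer passed and 43 turned sign. Many of the 1434 are edgeR settings, with 91 by the planned edgeR test alone. As edgeR recovers none, these losses tell nothing of stability either. By rank aggregation, 20 no longer passed with guides of 50 or more unsorted reads and 26 with a pseudocount of 10. With M1 alone 61 were lost and with M2 alone 59.

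Signs turned as follows, as log2 ratios or as log2 fold changes by edgeR or DESeq2, and the cause was not tested. Ranges with 1 library left out include edgeR fits in which 1 group holds a single guide library. Without the guides found in opposite gates Jak1 had -1.87 by ratio and -0.88 by edgeR in the double-high gate at low dose and -1.05 and -0.55 in the PD-L1-only gate. There Jak2 had -1.08 and -2.35, and -1.77 by edgeR, with no filter and with robust estimation, -2.07 by DESeq2, -1.72 with control-guide scaling, -1.58 without top guides, -1.94 with all 20 libraries and -3.68 to 3.92 with 1 library left out. Without top guides Mastl had -2.95, Kif18a -8.81, Rfx5 -0.75, unsorted Eftud2 -0.15 and, in the difference between doses, Rpl9 -6.44 and Srsf1 -2.23. With 1 library left out, Irf1 in the double-low gate ran from -0.56 to 2.04, Ifngr1 in the PD-L1-only gate from -1.74 to 2.58, Gins4 from -1.29 to 2.88 and Smarcb1 from -1.47 to 4.4. In unsorted cells Dhdds ran from -1.74 to 4.66, Nus1 from -4.01 to 8.59, Jak2 from -1.85 to 3.5 and Prpf38b from -0.3 to 8.08. In the difference between doses the ranges were -7.36 to 2.14 for Rpl9, -6.97 to 7.7 for Stub1, -5.81 to 5.74 for Ifngr2 and -7.1 to 6.68 for Jak2. Few sampled genomes, 16800 to 443900 by the Poisson model, limit all comparisons with a rarely filled gate.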

Other observations

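The tests of few unsorted reads as the source of the Urod call and of the alternatives named as such were chosen after the result was seen. Genes in the next paragraph were chosen after their values were seen too and belong to no fixed list.

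Several called genes of the high-dose comparison of the double-low with the double-high gate encode enzymes that build or use the sugar carrier of protein N-glycosylation in the endoplasmic reticulum. Dpagt1, which starts the lipid-linked sugar chain, had a log2 ratio of 2.58 ± 0.4 (SD, n = 2, adjusted p = 0.00111 by rank aggregation). Gmppb, which makes the mannose donor GDP-mannose, had 3.72 ± 0.73 (adjusted p = 0.0037), Dhdds, a subunit of the enzyme that makes the dolichol chain, 3.04 ± 1.26 (adjusted p = 0.0231), and Alg2, a mannosyltransferase of the pathway, 3.14 ± 0.61 (adjusted p = 0.0387). By limma, which called 17 unchanged genes higher in the simulation of this comparison and 25 genes in the data, or 6 without the replicate block, the adjusted p were 0.000938, 0.000271, 0.014 and 0.0245. Alg2 no longer passed with both directions adjusted together, and none of the 4 passed with M1 alone and only Gmppb with M2 alone. No list of the pathway was fixed before, so its members were not tested as a group.

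Urod was higher in the PD-L1-only gate at low dose, with 10 of 10 guides above 10 reads. Guides with fewer than 50 unsorted reads are argued against as the source, since the adjusted p was 0.000924 by rank aggregation without them. That cutoff does not remove guides of low starting abundance above it, so low abundance as such was not tested. Of the 1849 genes with the lowest unsorted abundance, 16.2% had an unadjusted p under 0.05 in the higher direction in this comparison. Loss of this enzyme may let fluorescent porphyrins collect that are read in the PD-L1 channel, and then loss of other enzymes whose substrates give such porphyrins would act alike. Of Uros, Cpox, Ppox and Fech 1 had an unadjusted p under 0.05 (Fech, 0.0141, one-sided), which is fewer than the 2 this explanation needs and more than the 0 that would exclude it. The fluorescence of the channel and a biological link of heme synthesis to PD-L1 stay open, as neither was measured.

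Core essential genes, a list of ribosome, proteasome and polymerase II genes, were called up by camera on the limma values in 6 comparisons of a rarely filled gate with a filled one, of which 0 held with an estimated correlation (adjusted p from 0.0752 to 0.418). Camera on edgeR counts called the list in none and pointed down in 4, and the list medians of the log2 ratio of summed CPM were -1.48, -3.31 and -1.69 at high dose and -0.54, -1.23 and 0.33 at low dose. Low starting abundance of their guides may account for the limma shift. In 0 of 6 comparisons did the list lie above the upper limit of 10000 lists of the same size matched on unsorted abundance. Matched genes came from the 100 neighbours on each side in unsorted abundance, and other essential genes were not left out. The test therefore cannot tell low abundance from loss of an essential gene. Mean shifts of the list were 0.74, 1.06, 0.85, 0.96, 0.73 and 0.42 on the log2 scale against 0.72, 0.97, 0.76, 0.72, 0.63 and 0.25 for matched lists (SD 0.11 to 0.12). The list lay above their mean in all 6, at percentiles 57.4, 79.5, 76.8, 97.3, 83.2 and 93.7, so a further small shift at low dose stays open. Among the 1849 genes with the lowest unsorted abundance, 5.5% to 16.2% had an unadjusted rank aggregation p under 0.05 in the higher direction, so calls of genes with low starting abundance carry that limit.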
